A study of Rattus norvegicus with 12 samples.

How the data were processed

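Total RNA (100 ng) of rat arterial smooth muscle cells, kept in 10% FBS and used 4 to 8 passages after transduction, was converted to biotin-labelled cRNA and hybridised to an Affymetrix rat 3' array, per the labels. The deposited values are log2 expression per probe set, made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes. The versions of both are not given in the sources used here. RMA corrects background, brings the arrays to 1 distribution and summarises the probes of a set, so a shift shared by most genes would be removed. The values have at most 2 decimals and no value is missing. The log scale was read from the value range, and the direction of every difference is versican V3 minus control vector.

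The table held 15923 probe sets on 12 arrays, and 57 Affymetrix control probe sets were left out, leaving 15866. Gene names came from the platform annotation, and 12783 probe sets had 1 gene, 312 had several and 2771 were unnamed here. Of the probe sets with 1 gene, 12748 matched a table of rat gene names of the assembly GRCr8 by gene identifier, 0 symbols changed, and 35 kept the platform's name. No gene was named from a probe set with several. A gene with several probe sets (10411 genes in all) was represented by the brightest over all arrays, except for versican, where all 5 are given. Coordinates were not used here.

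Technical replicates of experiment 1 were averaged per vector and the experiments were compared as pairs, as the series design describes. It does not say whether these replicates were separate transductions. Replicate arrays of experiment 1 correlated at 0.994 to 0.997 for the control vector and 0.992 to 0.997 for V3, and no pair was identical. Pairing was checked by the correlation of the deviations of each average from its vector's mean, which was 0.416, 0.480 and 0.257 within experiments 1, 2 and 3. All were over 0.1, and the values between different experiments ran from -0.386 to 0.093. These values go with the pairing by experiment number in the series design, but 3 averages per vector cannot establish it.

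The main test was limma 3.58.1 (lmFit and eBayes, R 4.3.3) on the 6 averages with the experiment as a block, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. There were 2 residual and 2.41 prior degrees of freedom, the median SE of a log2 fold change was 0.0893, and the smallest log2 change called was 0.52. Every adjusted p of a gene or probe set is from limma. Experiment 1 alone was tested with limma on its 8 arrays. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 21 lists. The list entries numbered 523, of which 429 matched a measured gene. The lists were contractile smooth muscle, inflammation and NF-kB targets, interferon response, elastic fibre, collagen, proteoglycan and hyaluronan, matrix protease and inhibitor, cell cycle, cholesterol synthesis, lipid uptake and storage, TGF-beta and BMP signalling, growth factor and receptor, osteochondrogenic, Wnt signalling, unfolded protein and integrated stress response, oxidative stress and detoxification, integrin and focal adhesion, and markers of endothelial, macrophage and leukocyte, fibroblast and adventitial, and Schwann and neural cells. Estimated correlations per list and fry were run beside camera. Figures were drawn with matplotlib 3.10.9.

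The groups, designs, lists, naming rule and alternatives, except the one that kept the control probe sets, were fixed before the data were examined. The rule named all versican probe sets, the 12 largest increases and 12 largest decreases among genes past the threshold with the same sign in 3 experiments, and in each list up to 4 members with the smallest unadjusted p. Genes named outside it (Nfkbia, Nfkb1, Il6, Vcam1, Cnn1, Lmod1, Sdc4, Ogn, Sdc3 and those first named in the closing section) were chosen after their values were seen. Alternatives covered the block, the handling of technical replicates, the variance model, scaling, a filter on dim probe sets, thresholds, each left-out experiment or array, the choice among probe sets of a gene and the list test.

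The steps were tested on simulated data with known changes. For the comparison over 3 experiments, 15866 probe sets were simulated and 20.9%, 94.0% and 100% of those changed by 0.5, 1 and 2 (log2) were recovered, with 11 false calls among 154. For experiment 1 alone the shares were 94.0%, 100% and 100%, with 15 false calls among 211. These shares came from 1 simulated data set per comparison, with normal noise and, over 3 experiments, the same change in each. They need not hold for real changes that vary between experiments. Adamts9, for example, had a log2 fold change of 2.66 that was not past the threshold (limma adjusted p = 0.0563). With 10411 simulated genes and no effect, 6 of 100 simulations gave a list call, and a list shifted by 0.5 was called in 100 of 100. Those simulated genes were independent of each other, unlike genes in cells.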

Results

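Gene expression was measured in cultured arterial smooth muscle cells of Fischer rats that carried 1 of 2 retroviral vectors. The versican V3 vector drives expression of the V3 splice form of versican, a large matrix proteoglycan, and V3 is the form that lacks the exons to which chondroitin sulfate chains attach. The control vector was empty. Each vector was used in 3 independent experiments. Experiment 1 held 4 technical replicate arrays per vector (A to D), and experiments 2 and 3 held 1 array per vector, which gave 6 arrays per vector and 12 in all. The values are log2 RMA signals of 15866 probe sets on a rat 3' expression array, and the array medians lay between 7.20 and 7.29. Levels below are mean ± SD over 3 experiments per vector (n = 3), with the 4 arrays of experiment 1 averaged first. The number of arrays limits the precision, and the p-values of experiment 1 alone measure the spread between its replicates, which the labels call technical without saying whether each was a separate transduction.

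The first comparison asked how the versican signal itself differed between the vectors. Of the 5 probe sets for Vcan, the versican gene, 1388142_at fell from 7.88 ± 0.23 to 6.57 ± 0.16 (2.49-fold lower, n = 3), with adjusted p = 0.0270 in limma. It was lower in each of the 3 experiments, by log2 differences of -1.41, -1.38 and -1.16. The probe sets 1371232_a_at and 1388054_a_at had higher means with V3, by 0.45 ± 0.13 and 0.49 ± 0.12 (log2 fold change ± SE). Both differences were positive in each of the 3 experiments but were not past the threshold in limma (adjusted p = 0.159 and 0.133). The remaining pair, 1371233_at and 1388265_x_at, had control means of 5.11 and 5.06, below the lowest quartile of the array at 5.97, and log2 fold changes of 0.11 and -0.01. In experiment 1 the values of 1371232_a_at were 10.25, 9.59, 10.40 and 10.25 in the V3 replicates A to D, against 9.38 to 9.46 in the control replicates. Which of these probe sets lie within the transferred V3 sequence is not given in the sources used here. A probe set outside it says nothing about the transgene. The call of versican 1388142_at was lost without experiment 1 (-1.27, adjusted p = 0.300 in limma) and without experiment 2 (-1.28, adjusted p = 0.0881).

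**Figure D1:**
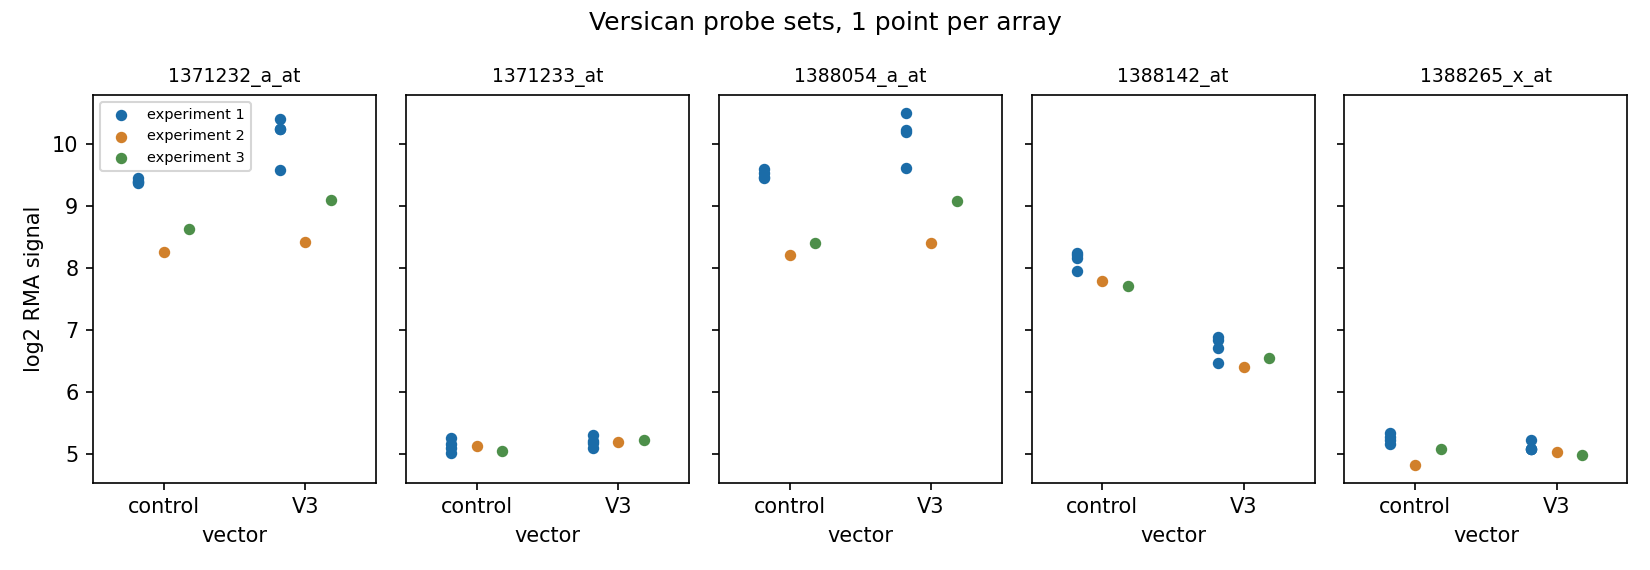
Log2 RMA signal of the 5 versican probe sets on each of the 12 arrays, by vector (horizontal axis) and experiment (colour), 1 point per array. The V3 arrays of 1388142_at lie between 6.41 and 6.90, below all control arrays of that probe set, which lie between 7.71 and 8.24.

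The second comparison asked which genes differed between V3 and control cells over the 3 experiments. Complement component C3 fell 115-fold, from 12.92 ± 0.32 to 6.08 ± 0.16 (n = 3, limma adjusted p = 0.00712), and Wfdc18, a whey acidic protein domain gene, fell 111-fold. The V3 mean of Wfdc18, 5.79, lay below the lowest quartile of the array at 5.97 and that of C3 close to it, so these folds are uncertain in size. The chemokine Cxcl1, which attracts neutrophils, fell 39.8-fold, and Lbp, the lipopolysaccharide binding protein, fell 30.5-fold. The chemokines Ccl20 and Ccl2, which attract lymphocytes and monocytes, fell 28.1-fold and 24.0-fold. The V3 means of Cxcl1 and Ccl20, 6.30 and 6.53, were also low, so their folds are uncertain in size too. The largest increases included Acta1, the skeletal form of alpha-actin, which rose 11.8-fold from 6.21 ± 0.58 to 9.77 ± 0.94 (n = 3, limma adjusted p = 0.0312). Its control mean lay close to the lowest quartile, so this fold is uncertain in size as well. Myl9, a regulatory myosin light chain of smooth muscle, rose 3.63-fold, and Fbln5, which binds elastin in elastic fibre assembly, rose 5.57-fold.

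In all, 335 of the 15866 probe sets changed at an adjusted p under 0.05 in limma, 164 higher and 171 lower with V3. They stood for 274 named genes, 128 higher and 146 lower. All 335 had the same sign in the 3 experiments, which the test itself favours. Changes over 2-fold were found for 70 probe sets that rose and 114 that fell, and changes over 8-fold for 3 that rose and 12 that fell. At an unadjusted p under 0.05 there were 3186 probe sets, against 793.3 expected by chance. The count was 219 without the experiment as a block, of which 171 were among the 335. It was 0 without experiment 1 (2050 at an unadjusted p under 0.05), 19 without experiment 2 and 229 without experiment 3. Each of these fits has 1 residual degree of freedom fewer, so that loss alone does not account for the counts of 0 and 19.

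Among the other large decreases, Serping1, the C1 inhibitor of the complement system, fell by 4.17 on the log2 scale, and Cd55, a membrane protein that limits complement activation, fell 7.68-fold. Ass1, the argininosuccinate synthase of arginine synthesis, fell 17.3-fold. Lcn2, an iron-siderophore binding protein of innate immunity, fell 14.4-fold, and Sod2, the mitochondrial superoxide dismutase, fell 7.75-fold. The V3 means of Lcn2, Serping1 and Cd55 (6.04, 6.20 and 6.50) were near the lowest quartile at 5.97, so their folds are uncertain in size. Il1rn, the interleukin 1 receptor antagonist, fell 7.05-fold. Over these 6 genes and the 6 fallen genes named above, the adjusted p-values in limma ran from 0.00548 for Wfdc18 to 0.0472 for Lbp.

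Among the other large increases, Aoc3, an amine oxidase of vascular smooth muscle, rose 8.13-fold, and Gpc6, a heparan sulfate proteoglycan of the cell surface, rose 7.35-fold. Spats2l rose 7.06-fold and Tmem204 rose 5.92-fold. Casq2, a calcium-binding protein of the sarcoplasmic reticulum, rose 5.58-fold. Gucy1b1, a subunit of the soluble guanylate cyclase that nitric oxide activates, rose 5.24-fold. Its control mean of 6.2 was near the lowest quartile, so this fold is uncertain in size. Olfml2b rose 5.09-fold. Myh10, a nonmuscle myosin heavy chain, rose 4.91-fold, and Dmpk, a protein kinase of muscle, rose 3.65-fold. The adjusted p-values of these 9 genes in limma ran from 0.0188 for Aoc3 to 0.0485 for Spats2l.

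**Figure D2:**
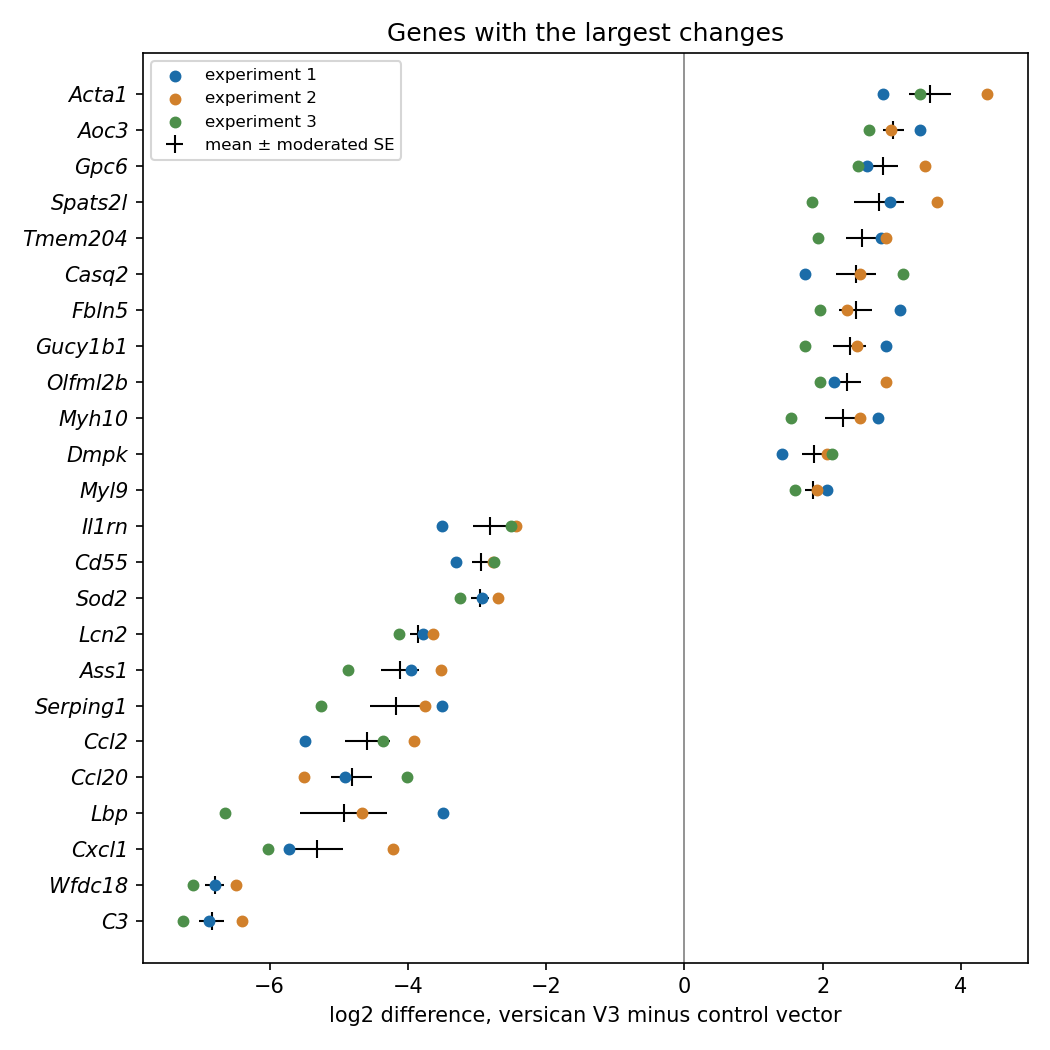
Log2 difference of versican V3 minus control vector (horizontal axis) for the 12 largest increases and the 12 largest decreases, 1 coloured point per experiment, with the mean and its moderated SE in black. All points of a gene lie on 1 side of 0, from -7.25 for C3 to 4.38 for Acta1.

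The third comparison asked whether groups of related genes shifted together. Of 26 measured inflammation and NF-kB target genes, 9 fell, 0 rose and 17 were not past the threshold, and 12 fell adjusted over the list alone. Besides C3, Cxcl1, Ccl20, Ccl2, Lcn2 and Sod2, the fallen members were Icam1, an adhesion molecule for leukocytes (from 11.30 ± 0.58 to 9.38 ± 0.62, n = 3, limma adjusted p = 0.00778), Nfkbia, the inhibitor of NF-kB, and Nfkb1, an NF-kB subunit. Il6 and Vcam1 had log2 fold changes of -1.37 and -1.61 that were not past the threshold (limma adjusted p = 0.249 and 0.194). The list median was -0.52, and the list shifted down by camera (adjusted p = 7.24e-10), a call lost with an estimated correlation (adjusted p = 0.397 with an estimated correlation). The median of the macrophage and leukocyte markers was 0.07, with 11 of 15 log2 fold changes positive, but 13 of the 15 lay below the median gene in control cells. The brightest, Cd14 and Lyz2, had log2 fold changes of -0.44 and -0.56 that were not past the threshold (limma adjusted p = 0.401 and 0.119).

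Of 20 measured contractile smooth muscle genes, 2 rose, 0 fell and 18 were not past the threshold, and 7 rose adjusted over the list alone. Acta2, the smooth muscle alpha-actin, rose from 12.52 ± 0.33 to 13.39 ± 0.10 (n = 3, limma adjusted p = 0.0497), and Cald1, the actin-binding caldesmon, rose from 11.86 ± 0.29 to 12.51 ± 0.17 (n = 3, limma adjusted p = 0.0481) at its brightest probe set, while its other probe sets had log2 fold changes of 0.01 and 0.07 (limma adjusted p = 0.988 and 0.671). All 20 log2 fold changes were positive, with a median of 0.45. Lmod1 and Cnn1 had log2 fold changes of 1.31 and 1.00 that were not past the threshold (limma adjusted p = 0.0829 and 0.0891). The list shifted up by camera (adjusted p = 1.29e-05), a call lost with an estimated correlation (adjusted p = 0.530 with an estimated correlation).

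Of 21 measured integrin and focal adhesion genes, 3 rose, 0 fell and 18 were not past the threshold, and 7 rose adjusted over the list alone. Vcl, which codes for vinculin of focal adhesions, rose 1.80-fold (limma adjusted p = 0.0310), Ptk2, the focal adhesion kinase, rose 3.10-fold (0.0337), and Flna, the actin crosslinker filamin A, rose 1.71-fold (0.0447). Itgb1, an integrin subunit counted as not past the threshold (0.48, limma adjusted p = 0.0552), was past it at its second probe set (0.57, adjusted p = 0.0451). The list median was 0.31, with an upward shift by camera (adjusted p = 0.000245) that was lost with an estimated correlation (adjusted p = 0.476 with an estimated correlation).

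A downward shift by camera was also found for 4 other lists, and each of these calls was lost with an estimated correlation (adjusted p = 0.601 with an estimated correlation for all 4). Of 21 interferon response genes, 2 fell, 0 rose and 19 were not past the threshold, with 3 fallen adjusted over the list alone, a median of -0.13 and camera adjusted p = 0.00764. The median of this list was -0.11, -0.25 and 0.05 in experiments 1, 2 and 3, so it was not negative in experiment 3. The fallen members were Psmb9, a subunit of the immunoproteasome (3.10-fold), and Gbp2, a guanylate-binding protein, whose V3 mean lay below the lowest quartile of the array. Of 22 genes of the unfolded protein and integrated stress response, 1 fell, 0 rose and 21 were not past the threshold, with 1 fallen adjusted over the list alone, a median of -0.31 and camera adjusted p = 0.000375. The fallen member was Ddit3, a stress-induced transcription factor (2.22-fold), and the list medians in experiments 1, 2 and 3 were -0.10, -0.065 and -0.62. Of 21 lipid uptake and storage genes, 3 fell, 0 rose and 18 were not past the threshold, while 2 rose and 6 fell adjusted over the list alone, with a median of -0.09 (-0.02, -0.09 and -0.30 in experiments 1, 2 and 3) and camera adjusted p = 0.0428. The fallen members were the transcription factor Cebpb, the lipid carrier Apoe and the fatty acid binding protein Fabp5. The second Apoe probe set, with means of 5.48 in control and 5.70 in V3 cells, had a log2 fold change of 0.22 (limma adjusted p = 0.350). Of 21 oxidative stress and detoxification genes, 0 were past the threshold in limma, also adjusted over the list alone, with a median of -0.29 (-0.05, -0.29 and -0.04 in experiments 1, 2 and 3) and camera adjusted p = 0.0428. The calls of the lipid and oxidative stress lists were lost in 7 and 9 of the 22 other settings.

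Camera called none of the 4 matrix lists. Of 17 elastic fibre genes, 3 rose, 0 fell and 14 were not past the threshold, with 3 risen and 2 fallen adjusted over the list alone and no call of the list by camera (adjusted p = 0.328). Eln, which codes for elastin, rose from 11.30 ± 0.44 to 13.05 ± 0.13 (n = 3, limma adjusted p = 0.0293), beside Fbln5 and the microfibril-associated Mfap4 (2.99-fold). Of 28 proteoglycan and hyaluronan genes, Gpc6 rose, 4 fell and 23 were not past the threshold, with 4 risen and 5 fallen adjusted over the list alone and no call by camera (adjusted p = 0.817). The fallen members were the small leucine-rich proteoglycans Prelp (4.11-fold) and Dcn (3.63-fold), the hyaluronan-binding Tnfaip6 (6.12-fold) and the cell surface proteoglycan Sdc4. Ogn and Sdc3 were past the threshold in limma only at a probe set other than the brightest and are not counted. Of 23 collagen genes, Col8a1, a short-chain collagen, rose 2.12-fold and 22 were not past the threshold, with 4 risen and 7 fallen adjusted over the list alone (camera adjusted p = 0.238). Of 24 matrix protease and inhibitor genes, Timp1, an inhibitor of matrix metalloproteinases, fell 2.38-fold and 23 were not past the threshold, with 2 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.817).

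Among signalling genes, Fst, the activin-binding follistatin, fell 5.66-fold, and Smad3, which transmits TGF-beta signals, fell 2.36-fold. The other 28 of 30 TGF-beta and BMP genes were not past the threshold, with 1 risen and 3 fallen adjusted over the list alone (camera adjusted p = 0.310). Of 32 growth factor and receptor genes, 3 fell, namely Vegfa, an angiogenic factor, Tgfa, an EGF receptor ligand, and Igfbp4, which binds insulin-like growth factors, and 29 were not past the threshold, with 3 risen and 4 fallen adjusted over the list alone (camera adjusted p = 0.526). Of 20 Wnt genes, Wnt4 fell 2.15-fold and 19 were not past the threshold, with 1 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.888). No member was past the threshold among 25 cell cycle, 15 cholesterol synthesis and 15 osteochondrogenic genes in limma (0 each), and camera called none of these lists (adjusted p = 0.604, 0.171 and 0.342). Adjusted over the list alone, 1 osteochondrogenic gene rose and 1 fell, against 0 in the other pair of lists. The cholesterol synthesis list had a median of -0.60 in experiment 1 and 0.33 in experiment 2. That of the cell cycle list was -0.06, 0.27 and -0.28 in experiments 1, 2 and 3, so its sign also changed between experiments.

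Markers of other cells that the cultures could hold were not called by camera. The adjusted p was 0.817 for 11 endothelial and for 15 macrophage and leukocyte markers, 0.0809 for 15 fibroblast and adventitial markers and 0.710 for 7 Schwann and neural markers. By the brightest probe set of each gene, Dcn was the only marker past the threshold in limma (1 of these 4 lists). At its second probe set, the endothelial marker Egfl7 was also past it (-0.70, limma adjusted p = 0.0407), against 0.0780 at the brightest. Adjusted over the list alone 1 endothelial and 1 fibroblast marker fell and 0 of the other markers changed. The median log2 fold changes were 0.06, 0.07, -0.16 and 0.08. Over all arrays, 8 of 11 endothelial and 7 of 15 macrophage and leukocyte markers had a mean under 5.97, the limit for dim probe sets. So had 2 of 15 fibroblast and adventitial and 3 of 7 Schwann and neural markers. Such markers had little room to fall. As a sign of RNA quality, the 3' minus 5' difference of the GAPDH control probe sets was 0.60 ± 0.26 in control and 0.63 ± 0.13 in V3 cells (log2, n = 3). It was 0.10 ± 0.10 and 0.22 ± 0.26 for beta-actin, with a V3 minus control difference of 0.30 in experiment 2, and 1.58 ± 0.16 and 1.65 ± 0.22 for hexokinase, with a difference of 0.21 in experiment 3.

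The list calls rest on a test that also called lists in other groupings of the same cultures. With the 6 averages split in the 9 other ways, camera called 3 to 8 lists, against 7 in the real split, and of the 7 called lists the inflammation list alone had a smaller p in the real split than in each of the 9 others. These other splits are not free of the vector difference, since each parts at least 1 of the 3 pairs of V3 and control cells. By fry, which tests a list without setting it against other genes, 2 lists shifted, inflammation and NF-kB targets down and integrin and focal adhesion up (adjusted p = 0.0227 each). Median, mean and test differed in sign for the matrix protease list (median 0.03, mean 0.02, camera down), the Wnt list (median 0.09, mean -0.03, camera down, fry up), the macrophage and leukocyte markers (median 0.07, mean -0.01, camera up) and the proteoglycan list (median 0.10, mean 0.02, camera up, fry down).

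**Figure D3:**
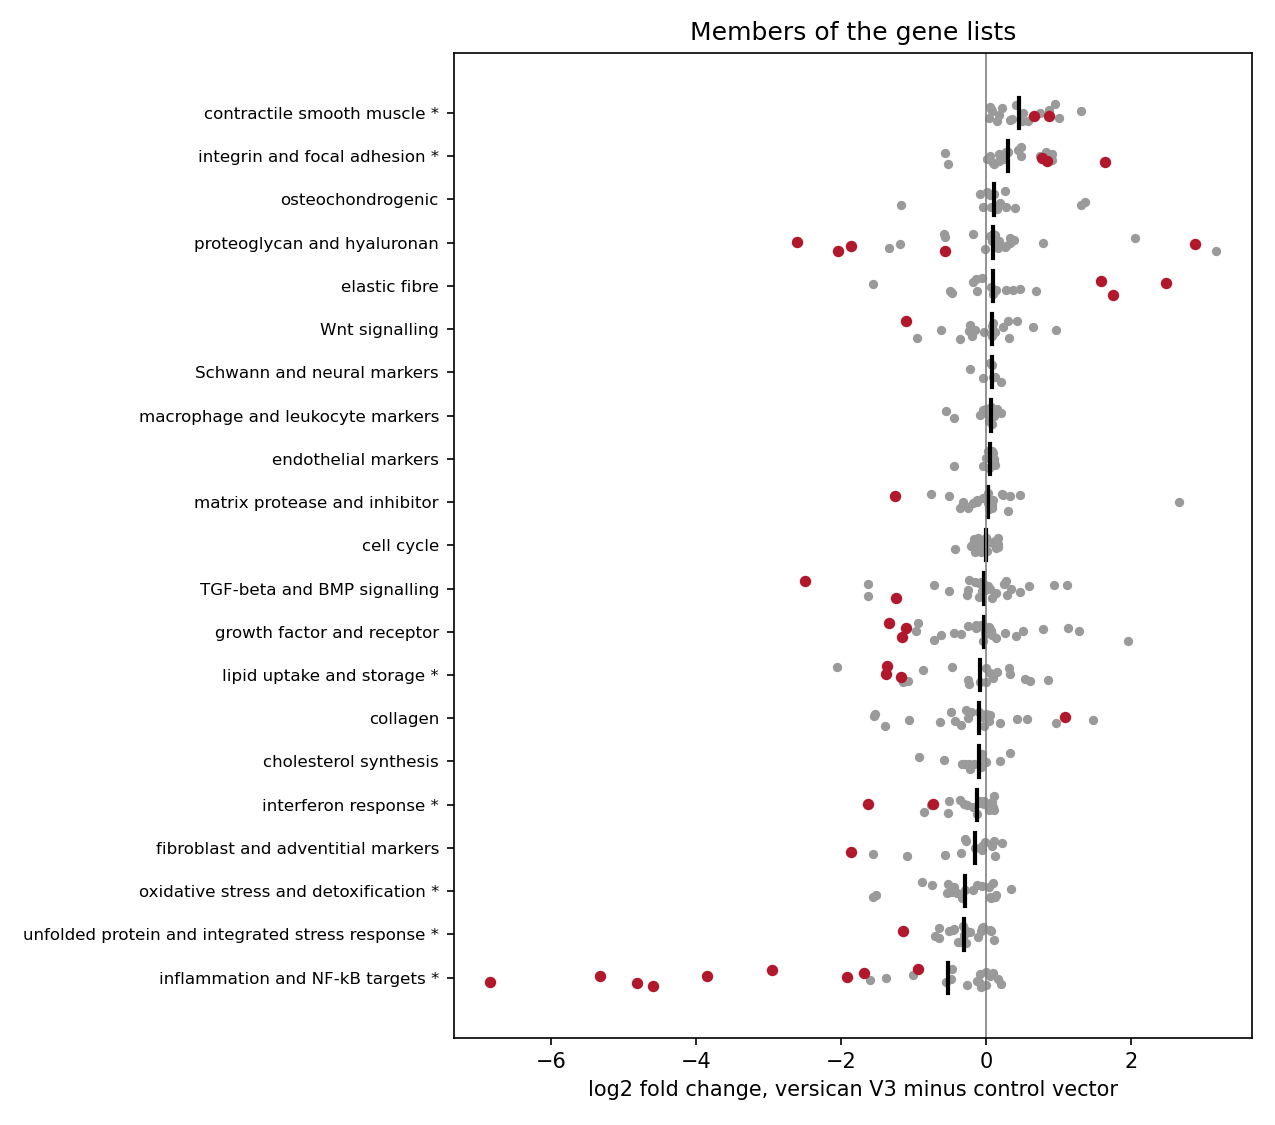
Log2 fold change of versican V3 minus control vector (horizontal axis) for the measured members of the 21 gene lists, 1 point per gene, with members past an adjusted p of 0.05 in red, the list median as a black bar and an asterisk on the 7 lists called by camera with the preset correlation. The inflammation list has 9 red points, all below 0, and the contractile list has all 20 points above 0.

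The fourth comparison asked how experiment 1 alone related to the other experiments. In experiment 1 the log2 differences were -6.87 for C3, -5.71 for Cxcl1, 2.88 for Acta1 and 2.06 for Myl9. In limma over its 8 arrays, 4917 probe sets differed at an adjusted p under 0.05, 2461 higher and 2456 lower with V3. They included all 335 probe sets called over the 3 experiments, a comparison that itself contains experiment 1, so this overlap is no independent support. Of the 4917, 63.3% had the same sign in both other experiments, against 37.9% of the 10949 probe sets not called in experiment 1. Of the 538 that were called and changed over 2-fold in experiment 1, 86.8% did. Across probe sets, which are not independent replicates, the differences correlated between experiments 1 and 2 with a Pearson r of 0.647 and a Spearman rho of 0.426. The values were 0.622 and 0.434 for experiments 1 and 3, and 0.588 and 0.419 for experiments 2 and 3.

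**Figure D4:**
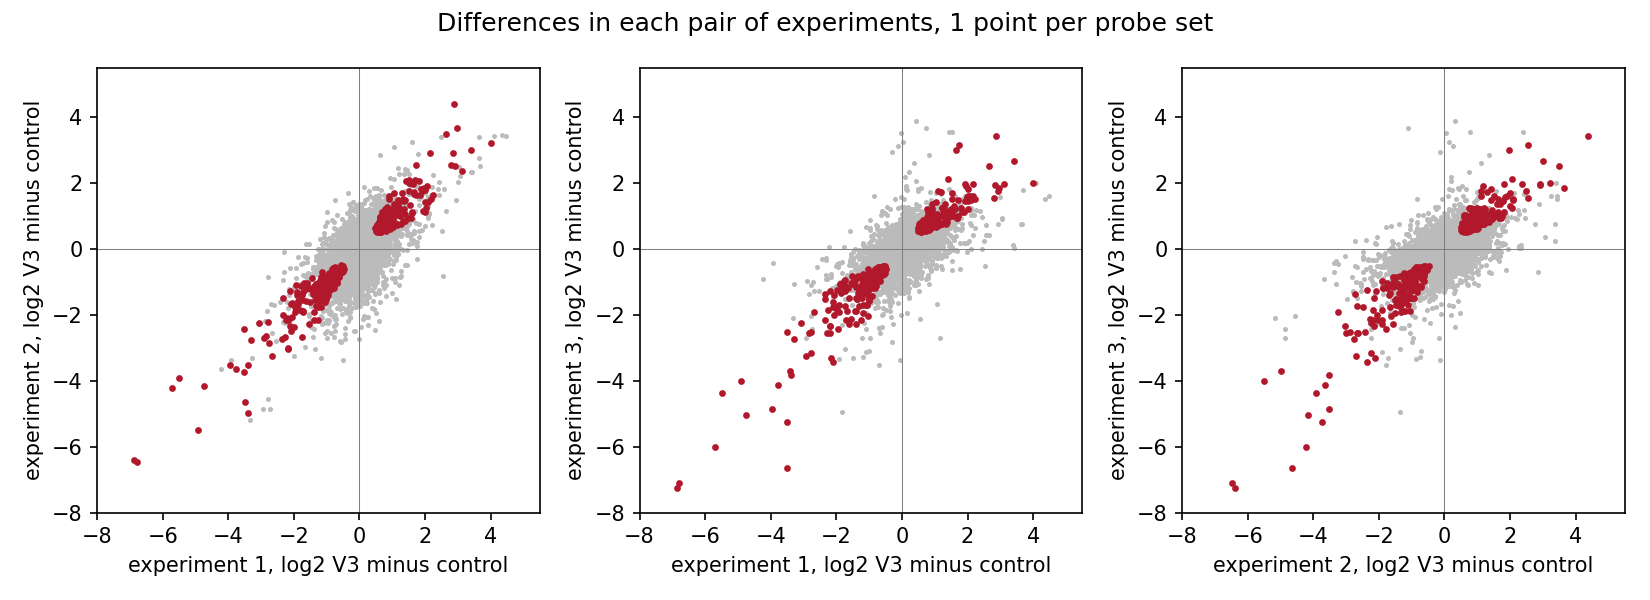
Log2 difference of versican V3 minus control vector in 1 experiment against another, 1 point per probe set, for each pair of experiments, with the 335 changed probe sets in red. The red points lie in the lower left and upper right of each panel, with Pearson r over all probe sets of 0.647, 0.622 and 0.588 from left to right.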

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

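The tests weighed here for the inflammation genes and the versican probe sets were chosen after those results were seen, as were the splits for single lists.

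Among the named genes and versican probe sets, 15 of 214 groups of 4 technical replicates of experiment 1 held an array far from its 3 fellows, against 10.7 by chance (about 1 in 20 groups). In V3 replicate 1A, Col5a1 was 12.01 (others 12.24 to 12.27), Dcn 8.02 (others 7.75 to 7.78) and Vcan 1388265_x_at 5.24 (others 5.08 to 5.09). In V3 replicate 1B, Ddit3 was 8.41 (others 8.07 to 8.10). In V3 replicate 1D, Cyp51 was 9.23 (others 9.54 to 9.56), Egfl7 9.23 (others 9.03 to 9.06), Gucy1b1 8.51 (others 8.72 to 8.76), Sod2 9.04 (others 9.32 to 9.33), Tcf7l2 8.11 (others 8.55 to 8.63) and Tgfb1 8.97 (others 9.25 to 9.30). In the control vector arrays, Fbln5 was 9.98 in 1B (others 9.68 to 9.73), Ccl20 11.43 in 1C (others 11.53 to 11.54), Prelp 11.91 in 1C (others 11.73 to 11.76), Sox10 6.07 in 1D (others 5.83 to 5.86) and Tgfb1 9.42 in 1D (others 9.69 to 9.71). All values are log2 signals.

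The 335 changed probe sets stand against a highest count of 0 in the 9 other splits of the 6 averages, 1 of 10 splits giving as many. For the gene lists the real value is 7 and the highest of the other splits 8, with 4 of 10 splits giving as many. The 10 splits are too few for a share under 0.05. In the 3 other splits that part all pairs, which turn the sign of 1 experiment, camera called 3 to 7 lists. The remaining splits part 1 pair and rest on the V3 difference of that experiment, so none of the others is free of the vector difference. In experiment 1 alone, 1 of 35 splits of the 8 arrays gave 4917 probe sets or more, and the highest other value was 0. Each of those other splits mixes the vectors, and the labels leave open whether the replicates were separate transductions, so what the count says about chance differences between cultures is not known.

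Of 26 inflammation and NF-kB target genes, 9 fell, 0 rose and 17 were not past the threshold, and the downward call of the list by camera is lost with an estimated correlation (adjusted p = 0.397). Leukocytes in the control cultures would lower leukocyte markers too, and although the median of 15 such markers was 0.072 (95% bootstrap interval -0.042 to 0.093, 10000 resamples), only 5 stood at least 0.5 over the limit of 5.97 for dim probe sets in control cells, a condition set after the result was seen, and the brightest, Cd14 and Lyz2, had log2 fold changes of -0.44 and -0.56, so leukocytes stay open. Under the other scalings the list median closest to 0 was -0.53. RMA had already brought the arrays to 1 distribution, so rescaling could move this median little and cannot weigh scaling as a cause. A single deviating experiment is argued against by list medians of -0.31, -0.51 and -0.805 in experiments 1, 2 and 3. The call by camera held without each experiment, but most other splits of the 6 averages gave it too, so it adds nothing here. The list's p was smaller in the real split than in the others, but camera also called it in 8 of the 9 others, each of which holds part of the vector difference. An effect of V3 stays open as a hypothesis.

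Versican 1388142_at fell, whereas 1371232_a_at and 1388054_a_at had positive differences that were not past the threshold over the 3 experiments. Under the other scalings the log2 fold change of 1388142_at closest to 0 was -1.33. Rescaling could move it little after RMA, so this cannot weigh scaling as a cause. Technical noise between arrays is argued against by experiment 1, where the largest adjusted p of the 3 probe sets in limma was 0.00559. For 1388142_at the fall recurred in experiments 2 and 3 (-1.38 and -1.16). For 1371232_a_at and 1388054_a_at the sign recurred, but by only 0.17 and 0.19 between the single arrays of experiment 2. Their V3 replicates in experiment 1 spanned 9.59 to 10.40 and 9.62 to 10.51, so signs this small do not argue against noise. A transgene signal at some probe sets beside a lower native transcript at 1388142_at may account for this, which was not tested, since the positions of the probes were not used here.

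Many calls of experiment 1 alone did not recur, and 63.3% kept their sign in both other experiments. In 100 simulations that added only the noise between replicates of experiment 1 to the effects of experiment 1, this share was 94.3% to 95.9%. The comparison sets single arrays against noise measured in 1 experiment, so noise of the single arrays in experiments 2 and 3 and real differences between experiments cannot be told apart. No biological explanation was tested.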

How the results depend on the processing

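The setting that kept the control probe sets (335 changed probe sets) was chosen after seeing the data, and the others before. The cause of each change below was not tested, except where fewer samples or another threshold make it. The 335 changed probe sets became 219 without the paired replicate block (171 shared), 2944 with all 12 arrays and duplicateCorrelation, 216 with technical replicate A alone, 1094 with averages weighted by their arrays, 971 at an adjusted p under 0.10 and 1033 at an unadjusted p under 0.05 and 1.5-fold. The counts of 2944 and 1094 lean on the technical replicates of experiment 1, which are not independent experiments. They do not show that more probe sets changed over the 3 experiments. Leave-outs gave 0 (without experiment 1) to 365, with 19 without experiment 2 and 229 without experiment 3. The 49 named genes past the threshold kept their call in 33 cases without the block, 40 with replicate A alone, 0 without experiment 1, 7 without experiment 2 and 35 without experiment 3. The probe sets versican 1371232_a_at and 1388054_a_at passed the threshold with duplicateCorrelation (0.52 and 0.53), and the latter with weights (0.56). These calls carry the same limit, since they too lean on the technical replicates of experiment 1. Leave-outs gave -1.39 to -1.27 for 1388142_at and -0.12 to 0.055 for 1388265_x_at, whose sign turned, also with replicate A alone (0.06). List calls numbered 0 with an estimated correlation and 2 by fry, and 5 to 9 otherwise, and the block changed 1 list call, that of oxidative stress genes. Camera's direction turned only in lists it had not called, with these medians. For the macrophage and leukocyte markers list it was 0.050 with duplicateCorrelation, -0.037 with replicate A alone, 0.033 with weights, 0.025 with quantile normalization again and 0.040 without dim probe sets. For the endothelial markers list it was 0.034, 0.033 and 0.0081 with duplicateCorrelation, replicate A alone and quantile normalization. For the proteoglycan and hyaluronan list it was 0.062 with duplicateCorrelation and 0.048 with replicate A alone, and for the Schwann and neural markers list 0.033 with replicate A alone. By fry, the proteoglycan and hyaluronan list (0.099) and the Wnt signalling list (0.086) went the other way. Leave-outs turned the matrix protease and inhibitor list (-0.028 to 0.078), the cell cycle list (-0.18 to 0.12), the cholesterol synthesis list (-0.45 to 0.065), the Wnt signalling list (0.037 to 0.085), the endothelial markers list (0.018 to 0.10) and the macrophage and leukocyte markers list (0.011 to 0.11). With replicate A alone, the correlations of experiment 1 with 2 and 3 were 0.559 and 0.507. Dim probe sets near the background, under 5.97, limit what the arrays can show. For experiment 1 alone, the other settings gave 4291 to 5188 probe sets.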

Other observations

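The tests of the 3 groups below were written before their values were seen, on members that had not been seen among the changed genes, whereas the splits and the groups themselves were chosen after the changed genes were seen. The demand that a call also hold with an estimated correlation and stand apart from the other splits was added after the first p-values were seen, and ended the calls of the first pair of groups.

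Of 39 measured genes of glycolysis and the response to low oxygen, 9 fell, 0 rose and the others were not past the threshold in limma. All 9 were among the changed genes from which the group was chosen, so this count is no support for a shared fall. The fallen genes were Higd1a (-1.44), Adm (-1.41), Pfkp (-1.31), Vegfa (-1.11), Tpi1 (-0.97), Slc2a1, a glucose transporter (-0.90), Ldha, the lactate dehydrogenase A (-0.82), Pgk1 (-0.74) and Ero1a (-1.78), as log2 fold changes. Of 28 members not seen before, 26 had negative log2 fold changes, with a median of -0.52. That 0 were past the threshold follows from leaving the changed genes out of these members. A fall of hypoxia and glycolysis genes as a group had a camera adjusted p of 1.76e-10 on these 28, but 0.134 with an estimated correlation. Of the 10 splits of the 6 averages, the real one included, 9 had a p under 0.05 and 3 a p no larger than the real one, and the others hold part of the vector difference. Since the call is lost with an estimated correlation, a shared response to the vector cannot be told apart from genes that vary together between cultures.

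Of 45 measured genes of caveolae, cGMP signalling and the muscle cytoskeleton, 16 rose, 0 fell and the others were not past the threshold in limma. All 16 were among the changed genes from which the group was chosen, so this count is no support for a shared rise. Cav1 and Cav2, which form caveolae, rose by 0.70 and 1.22 on the log2 scale, Gucy1a1, the partner of Gucy1b1, by 0.64 from a control mean below the lowest quartile of the array, Itpr1, a calcium release channel, by 1.23, and Sorbs2 by 1.75. Of 28 members not seen before, 20 had positive log2 fold changes, with a median of 0.21. Here too, 0 past the threshold follows from leaving out the changed genes. Camera gave an adjusted p of 0.00340 on these 28 and 0.134 with an estimated correlation. The p was smaller in the real split than in the 9 others, the lowest other being 0.00326 unadjusted against 0.00227, and 10 splits are too few for a share under 0.05. Of the 10 splits, the real one included, 6 had a camera p under 0.05. A shared rise remains a hypothesis.

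Among complement genes, C1s (-1.21) and Clu (-1.56) fell beside C3, Serping1 and Cd55, and Cd59b rose (1.31), as log2 fold changes. The 13 members not seen before had a median of 0.07, with 10 positive, and camera gave an adjusted p of 0.324. Most had low control means, such as 5.24 for Cfd and 6.11 for Cfi, and so little room to fall. The brightest of the 13, C1r, went from 11.12 to 10.29 (-0.83), not past the threshold (limma adjusted p = 0.0513). The changed genes were left out of the 13 members, so the camera test leaves open whether the complement genes fell as a group.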
